A study of Mus musculus with 9 samples.

How the data were processed

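Total RNA from mouse prefrontal cortex was extracted with Trizol and made into stranded libraries after ribosomal RNA depletion, per the labels' protocols. Per the submitters' processing notes, cutadapt, TopHat2 and HTSeq were used with the mm9 build; versions, the normalization and the strand setting are not given in the sources used here. The deposited values are a non-negative signal per gene, named by the authors as CPM, with 1 column for each of the 9 libraries, and 9 of 9 single-library files equalled the matrix.

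These values were not plain CPM. None of them was 0, and of the 255 ways to divide the libraries into 2 sets, a single one gave equal mean log2 values in both sets for every gene, to within 2.5e-09, while the next best reached a largest difference of 0.87. The sets were the wild-type libraries with UNC0642 replicates 2 and 3 (5 libraries) and the saline mutant libraries with UNC0642 replicate 1 (4 libraries). No label mentions this step or a batch. As a result, the log2 difference between saline mutant and wild type is fixed by the deviations of the 3 UNC0642 libraries, to within 3.7e-09, and the other 2 differences between group means are too, to within 1.8e-09.

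Whole reads were recovered by solving, for each gene, for the 1 shift between the sets at which all 9 values become whole reads after removal of a prior of 3.0 reads on average, which gives a value of 0.2187 to 0 reads. A single solution was found for 14444 of 14444 genes, with 100% of values whole within a tolerance of 0.02 reads and a largest distance of 4e-05 reads. The recovered reads came to 12035098, 13267359 and 12445073 for wild type, 12548293, 15227237 and 14345248 for saline mutants and 12233543, 16165483 and 15139774 for UNC0642. In simulated data of 3000 genes the solving step returned 100% of genes exactly when given the sets, the prior and the value of 0 reads. Finding these from the values was not tested in this way. The largest log2 difference between the deposited values and those rebuilt from the recovered reads was 0.00076.

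The design fixed before the data were examined foresaw a count test on raw reads, with groups, comparisons, gene lists, alternatives and the rule for naming genes. As the values were not counts, limma 3.58.1 (R 4.3.3) with an intensity trend was used on log2(value + 0.5), with all 9 libraries, the group as the only term and Benjamini-Hochberg adjustment; genes were called at an adjusted p under 0.05. Fold changes are on the log2(value + 0.5) scale, which understates changes of low genes. No gene was removed. edgeR and DESeq2 were not used. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry; 38 lists were fixed, 37 could be tested, and 906 of their 1024 members were measured. Symbols, gene types and chromosomes came from GENCODE M21 for 13895 of 14444 symbols, and no coordinates are given because that annotation is on another build than mm9.

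Named genes were, for each comparison with fewer than 10 genes called, the 10 of smallest p, then Shank3, Ehmt1, Ehmt2 and Arc, and up to 4 members of smallest p for each list described; 2 of these genes and 1 of the lists are not reported here. Other genes were named after their values were seen, namely those of the library division and those called by an alternative that called 5 or fewer. Scores of marker lists were compared by exact two-sided permutation tests. Alternatives among those choices were median-of-ratios and upper-quartile factors, limma-voom on the reads (here the recovered reads), a value of at least 1 in at least 3 libraries (14425 genes), only the 2 groups compared, a replicate block, leaving out each library, an adjusted p under 0.1, a fold of at least 1.2, and saline mutant libraries divided between the comparisons. Alternatives added after seeing the data were other pseudocounts, the adjusted set as a term, the recovered reads with and without their division as a term, the adjustment made again with UNC0642 replicate 2 in the other set, and libraries on 1 side of the division. The limma step was tested on simulated data with 200 changed genes. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.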

Results

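Total RNA was sequenced from the prefrontal cortex of mice aged 5 to 8 postnatal weeks, after ribosomal RNA depletion, in 9 libraries of 3 groups. Shank3 encodes a scaffold protein of the excitatory postsynapse, and the labels name the mutant genotype without the allele. The groups were wild-type mice given saline, Shank3 mutant mice given saline and Shank3 mutant mice given UNC0642, with 3 libraries in each. UNC0642 inhibits the histone methyltransferases EHMT1 and EHMT2, which place mono- and dimethyl marks on lysine 9 of histone H3; it was injected intraperitoneally at 1 mg per kg once a day for 3 days. The deposited values covered 14444 genes, and each library summed to between 975390 and 1028773. Whole reads behind these values, recovered by the procedure given with the processing, came to between 12035098 and 16165483 per library. Nothing in the labels says whether the 3 libraries of a group came from separate animals, so p-values measure the spread between libraries, which may be technical.

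The deposited values carry an adjustment that bears on all 3 comparisons. For each gene, the mean log2 value of the 3 wild-type libraries and UNC0642 replicates 2 and 3 equalled that of the 3 saline mutant libraries and UNC0642 replicate 1, to within 2.5e-09. A log2 change of 1 present in the saline mutant libraries alone keeps 0.25 of its size under such an adjustment, and a change of 1 kept under UNC0642 shows as 0.40 in the saline mutants and 0.80 in the treated ones. Between UNC0642 and saline mutants, the kept change then shows as 0.4 in place of 0. A full reversal by UNC0642 shows as -0.5 in place of -1. In simulated data without the adjustment, limma called 187 of 200 genes with a log2 change of 1 between saline mutant and wild type (14444 genes tested); after the adjustment it called 0 of 200. The absence of calls between saline mutant and wild-type libraries thus says nothing about changes of that size. Presence says little either: by the adjustment the mean of saline mutant minus wild type is fixed by the deviations of the 3 UNC0642 libraries, as are the other 2 differences, and a change of 1 under UNC0642 alone shows there as 0.15.

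The recovered reads, which precede the adjustment, fell into a division that differed from the adjusted sets by a single library. Mrgpra6, a receptor gene of sensory neurons, had 2299, 3100 and 3895 reads in the wild-type libraries and 3749 in UNC0642 replicate 3, against 0 in the other 5. Lrrc17 had 1546, 1960 and 1551 reads in the wild-type libraries and 2506 in UNC0642 replicate 3, against 7 to 14 elsewhere. Eno1b and the pseudogene Morf4l1-ps1 ran the other way, with 706 to 962 and 467 to 701 reads in the saline mutant libraries and UNC0642 replicates 1 and 2, and with 0 to 2 and 0 reads in the rest. In all, 19 genes lay at least 8-fold apart between every wild-type and every saline mutant library, and UNC0642 replicate 3 lay with the wild type for 19 of them while replicates 1 and 2 did so for 0. The first principal component of the recovered values, with 51.7% of the variance, divided the libraries in this way, so genotype and division can be told apart through UNC0642 replicate 3 only.

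**Figure D1:**
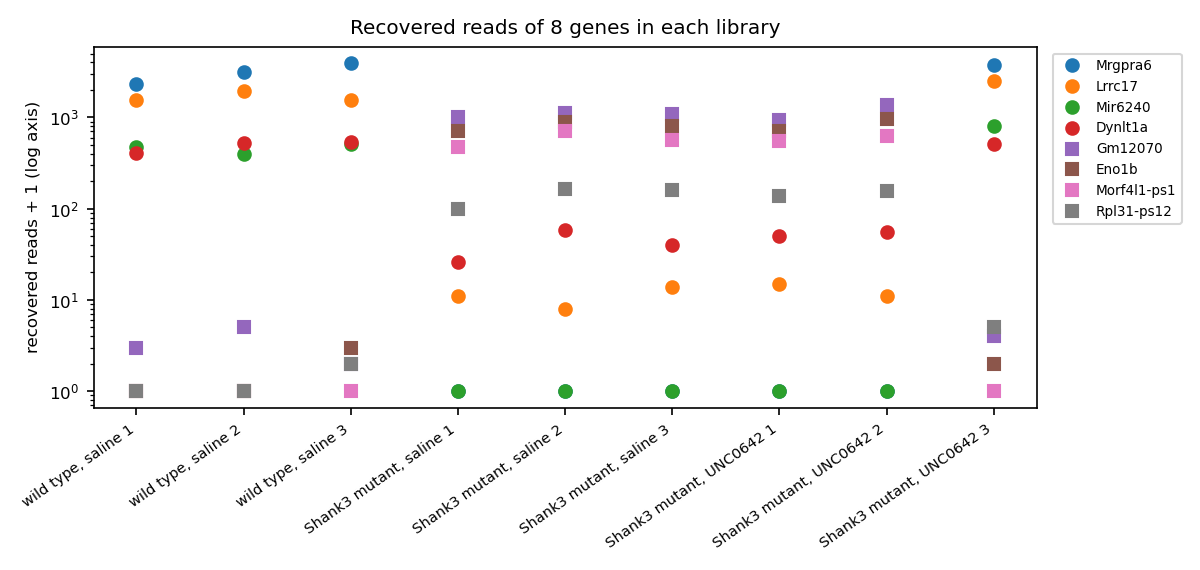
Recovered reads plus 1 (log axis) of 8 genes in each of the 9 libraries; circles are genes higher in the wild-type libraries and squares genes higher in the saline mutant libraries, and symbols overlap where values coincide. UNC0642 replicate 3 lies with the wild-type libraries for all 8 genes, with 3749 reads of Mrgpra6 against 0 in the saline mutant libraries.

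The mutated gene and the targets of the compound were compared first. Shank3 was read at 308, 315 and 355 in the wild-type libraries, at 333, 343.5 and 318 in the saline mutants and at 288, 303 and 322.5 under UNC0642. Ehmt1 lay at 36.2 ± 0.473, 35.6 ± 1.86 and 34.7 ± 1.41 (SD, n = 3 each) in these groups, and Ehmt2 at 228 ± 18.05, 234 ± 8.22 and 228 ± 8.94 (SD, n = 3 each). Shank3 was not called between saline mutant and wild type (log2 fold change 0.03, SE 0.08, limma adjusted p = 1), but a gene total checks the genotype only where the allele removes exons of the transcript, which the labels do not say. Arc, an activity-regulated gene of the postsynapse, had 418 ± 33.9, 326 ± 45.5 and 298 ± 88.2 (SD, n = 3 each). Its log2 fold change was -0.37 (SE 0.19) in saline mutant against wild type and -0.53 (SE 0.19) in treated mutant against wild type, with limma adjusted p of 1 and 0.59. All these deposited differences are fixed by the 3 UNC0642 libraries, so they do not measure genotype or treatment directly. In recovered reads of the mutant libraries on 1 side of the division (2 UNC0642, 3 saline), UNC0642 was compared with saline. Shank3, Ehmt1, Ehmt2 and Arc differed by -0.2, -0.01, -0.16 and -0.11 (SEs 0.06, 0.1, 0.06 and 0.3), none called.

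**Figure D2:**
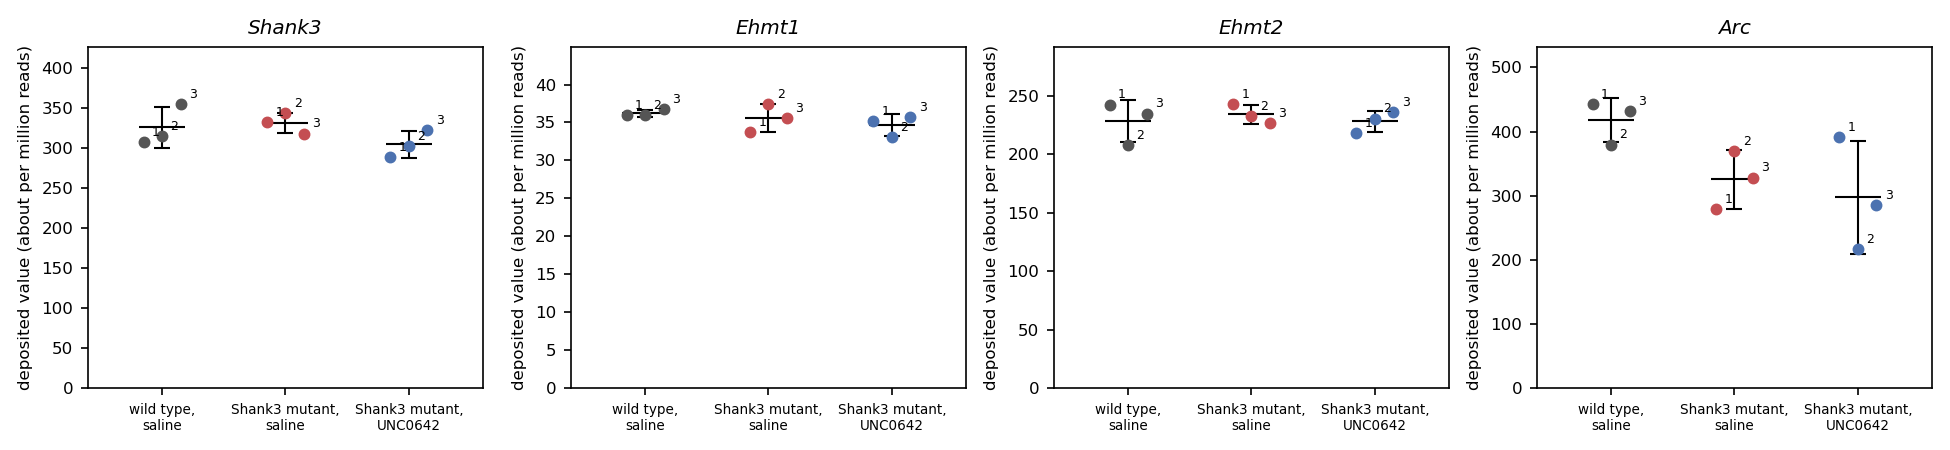
Deposited values (vertical axes, from 0) of Shank3, Ehmt1, Ehmt2 and Arc in each library, with points numbered by replicate, and the mean (bar) and SD (whiskers) of each group of 3. Arc has group means of 418, 326 and 298, and the log2 fold changes of the other 3 genes lie between -0.12 and 0.04.

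Saline mutant libraries were compared with saline wild-type libraries. As the deposited difference is a fixed combination of the UNC0642 libraries (replicates 2 and 3 less replicate 1), the list directions and p-values below describe the deposited values and do not test the genotype. Meningeal fibroblast markers, genes of the membranes around the brain, were higher in the deposited values of the mutant libraries, with 19 of 19 members positive and a median log2 fold change of 0.40 (camera adjusted p = 1.1e-16, and adjusted p = 0.67 with an estimated correlation between members). Col3a1, a fibrillar collagen, differed by 0.53 (SE 0.26), the transporter Slc13a4 by 0.52 (SE 0.26), the proteoglycan Dcn by 0.38 (SE 0.20) and the GABA and taurine transporter Slc6a13 by 0.42 (SE 0.23), none of them called. Cytosolic ribosomal protein genes (61 of 66 positive, median 0.06, camera adjusted p = 1.25e-08) and nuclear-encoded oxidative phosphorylation genes (53 of 56 positive, median 0.05, camera adjusted p = 0.00059) were slightly higher, at adjusted p = 0.95 and 0.96 with an estimated correlation. Rplp1 and Ndufa2 both stood at 0.15, with SEs of 0.11 and 0.12.

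Lower in the deposited values of the saline mutants were heat shock and unfolded protein response genes (22 of 24 negative, median -0.07, camera adjusted p = 8.3e-05), nuclear-retained long RNAs (10 of 10 negative, median -0.14, adjusted p = 0.00035) and immediate early genes (27 of 35 negative, median -0.08, adjusted p = 0.00097), each at adjusted p = 0.67 with an estimated correlation. The chaperone cofactor Chordc1 had a log2 fold change of -0.22 (SE 0.12), the microRNA host Mirg -0.31 (SE 0.19), Inhba -0.33 (SE 0.22) and Egr3 -0.26 (SE 0.19). Voltage-gated channel genes (32 of 39 negative, median -0.05), histone lysine methylases and demethylases other than those of H3K9 (23 of 29 negative, median -0.06) and autism risk genes (37 of 50 negative, median -0.04) were also lower in camera, with adjusted p of 0.00097, 0.0022 and 0.0036, against adjusted p = 0.67, 0.95 and 0.95 with an estimated correlation. Kcna1 lay at -0.17 (SE 0.10), and Kmt2c and Kmt2a at -0.19 each (SEs 0.13 and 0.14). Glutamate receptor and postsynaptic scaffold genes (21 of 40 positive, camera adjusted p = 0.75) and genes that write, erase or read H3K9 methylation (12 of 30 positive, adjusted p = 0.28) were not called. With an estimated correlation 0 of the 37 lists were called, fry also called 0. Without wild-type replicate 2 or 3 the number called was 5 or 16 in place of 10. In the recovered reads with the division as a term, where UNC0642 replicate 3 is the only link to wild type, meningeal markers had a median of 1.30 (adjusted p = 1.2e-26, and adjusted p = 0.3 with an estimated correlation). The calls ended there for immediate early genes (0.01, adjusted p = 0.96), autism risk genes (0.02, 0.72), other methylases (-0.06, 0.78) and oxidative phosphorylation (0.01, 0.9). The number called there was 15 in place of 10, with glutamate receptor and scaffold genes (0.08, adjusted p = 0.00777), circadian genes (0.13, 0.0171), hippocampal markers (0.43, 0.00883) and small RNAs (0.74, 0.000176) gained, each at adjusted p = 0.3 with an estimated correlation. Microglia (0.26, 0.00272) and olfactory or immature neuron markers (0.35, 0.00699) were gained too, at adjusted p = 0.66 with an estimated correlation. Deep-layer, upper-layer, oligodendrocyte and astrocyte markers were also gained, at adjusted p = 0.53, 0.3, 0.66 and 0.6 with an estimated correlation.

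The 10 genes of smallest p, none called, were Gabra2, Inf2, Mgp, Gpr39, Lypd1, Tanc1, Gse1, Serinc2, Bche and Prss23. Gabra2, a GABA-A receptor subunit, had 64.55 ± 4.67 in wild type and 48.9 ± 2.08 in saline mutants (SD, n = 3 each), a log2 fold change of -0.40 (SE 0.14). The formin Inf2 had 130.3 ± 12.6 and 107 ± 4.58, and the matrix protein gene Mgp 9.001 ± 0.866 and 12.8 ± 1.15 (SD, n = 3 each), log2 fold changes of -0.28 (SE 0.11) and 0.48 (SE 0.20). Gpr39, Lypd1 and Bche stood at 0.28, 0.27 and 0.54, and Tanc1, Gse1, Serinc2 and Prss23 at -0.44, -0.26, -0.57 and -0.30. In limma on log2(value + 0.5), 0 genes were called at an adjusted p under 0.05 in either direction, and 13 had an unadjusted p under 0.05. The 13 are a smaller share of the 14444 genes than the 0.05 that no change would give. With the spread taken from these 6 libraries alone, 5 were called, Mrgpra6 and Lrrc17 lower and Gm12070, Eno1b and Morf4l1-ps1 higher, each of them on 1 side of the division. In limma-voom on the recovered reads, which has no adjustment and takes the division as genotype, 820 genes were higher and 938 lower.

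**Figure D3:**
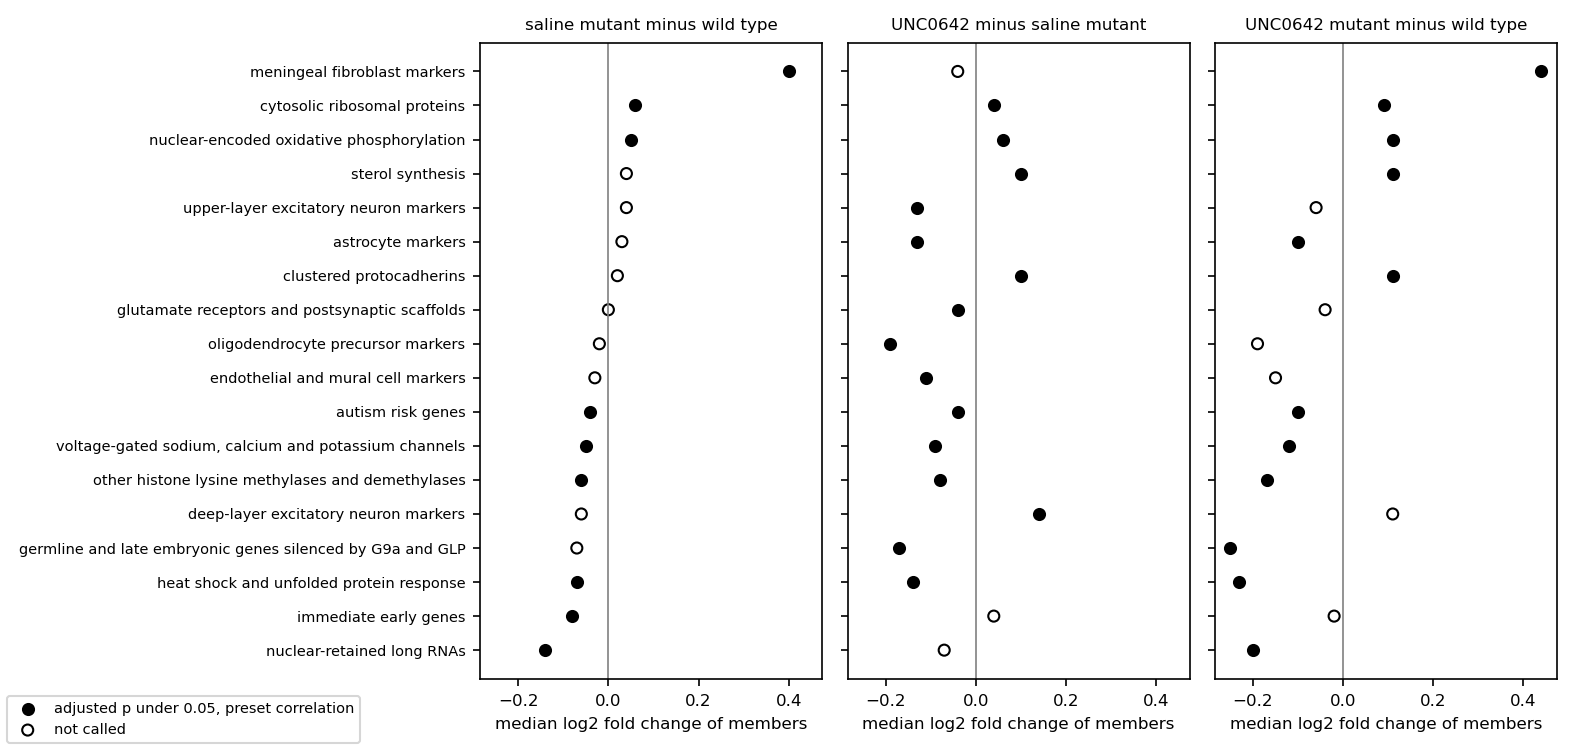
Median log2 fold change (horizontal axes) of the members of 18 gene lists called in at least 1 comparison, with the 3 comparisons side by side; filled points have a camera adjusted p under 0.05 with the preset correlation and open points do not. Meningeal fibroblast markers stand at 0.40 and 0.44 in the mutant groups against wild type and at -0.04 between the mutant groups.

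The effect of EHMT1/2 inhibition was asked by comparing UNC0642 with saline in the mutants. In the deposited values, a mutant change that UNC0642 leaves as it is shows in this comparison as 0.4 of its size. The list directions and p-values below therefore describe the deposited values and do not by themselves test the treatment. Sterol synthesis genes were higher after UNC0642, with 23 of 23 members positive and a median log2 fold change of 0.10 (camera adjusted p = 0.00017, and adjusted p = 0.47 with an estimated correlation). Fdft1, which encodes squalene synthase, differed by 0.19 (SE 0.09), Msmo1 by 0.14 (SE 0.08) and Tm7sf2 by 0.20 (SE 0.12). Deep-layer excitatory neuron markers were higher (15 of 19 positive, median 0.14, adjusted p = 0.015), with Crym at 0.32 (SE 0.15), Foxp2 at 0.28 (SE 0.16) and Fezf2 at 0.25 (SE 0.14), while upper-layer markers were lower (12 of 15 negative, median -0.13, adjusted p = 0.015), with Kcnip2 at -0.26 (SE 0.10) and Cux1 at -0.17 (SE 0.09). Clustered protocadherins were higher (35 of 53 positive, median 0.10, adjusted p = 0.015), Pcdhga11 by 0.32 (SE 0.14) and Pcdhb6 by 0.57 (SE 0.26), with Pcdhgb2 at -0.37 (SE 0.18). Both layer lists and the protocadherins had adjusted p = 0.70 with an estimated correlation.

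Heat shock and unfolded protein response genes were lower after UNC0642 (19 of 24 negative, median -0.14, camera adjusted p = 0.00043), among them Sdf2l1 at -0.47 (SE 0.17), Manf at -0.21 (SE 0.10) and the endoplasmic reticulum chaperone Hspa5 at -0.24 (SE 0.13). This list and the others of this paragraph had adjusted p = 0.70 with an estimated correlation. Astrocyte markers were lower (21 of 23 negative, median -0.13, adjusted p = 0.00088), S100b by a log2 fold change of -0.22 (SE 0.08), as were endothelial and mural markers (18 of 26 negative, median -0.11, adjusted p = 0.015), Flt1 by -0.43 (SE 0.15), and oligodendrocyte precursor markers (9 of 13 negative, median -0.19, adjusted p = 0.038), Olig2 by -0.38 (SE 0.15). Voltage-gated channel genes were lower (29 of 39 negative, median -0.09, adjusted p = 0.0039), with Scn8a at -0.13 (SE 0.08), and so were glutamate receptor and scaffold genes (28 of 40 negative, median -0.04, adjusted p = 0.029), Cacng2 by -0.26 (SE 0.10). Of 32 germline genes silenced by EHMT1/2 only 7 were measured, and these were lower (7 of 7 negative, median -0.17, adjusted p = 0.029), Ddx4 by -0.50 (SE 0.24). Other histone lysine methylases (21 of 29 negative) and autism risk genes (35 of 50 negative) had medians of -0.08 and -0.04, at adjusted p of 0.029 and 0.038. With the division as a term the calls ended for germline genes (-0.01, adjusted p = 0.4), channels (0.00, 0.30) and other methylases (-0.01, 0.35). They also ended for autism risk genes (-0.02, 0.19), precursor markers (-0.06, 0.30) and endothelial markers (-0.04, 0.16). Within the 5 mutant libraries on 1 side of it, 3 of 7 germline genes and 20 of 39 channel genes were positive.

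Oxidative phosphorylation (50 of 56 positive) and ribosomal protein genes (54 of 66 positive) had medians of 0.06 and 0.04 after UNC0642, at camera adjusted p of 0.0039 and 0.016, against adjusted p = 0.71 and 0.74 with an estimated correlation. With the division as a term they stood at -0.01 (adjusted p = 0.34) and -0.07 (adjusted p = 6.1e-07, and adjusted p = 0.39 with an estimated correlation). In limma-voom on the recovered reads these lists turned, to medians of -0.11 and -0.10, as did other histone methylases (0.06), autism risk genes (0.05), oligodendrocyte precursor markers (0.12) and endothelial markers (0.02). H3K9 methylation genes (12 of 30 positive, adjusted p = 0.29) and immediate early genes (25 of 35 positive, adjusted p = 0.19) were not called. Meningeal markers, at a median of -0.04, reached -0.27 with the division as a term (adjusted p = 0.00091, and adjusted p = 0.43 with an estimated correlation). Of the 37 lists 0 were called with an estimated correlation and 0 by fry. Without UNC0642 replicate 2 the number called was 3 in place of 15.

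The 10 genes of smallest p between UNC0642 and saline mutants, none called, were A930005H10Rik, Acan, Dynlt1b, Cntnap4, Lrrc38, Adgrl4, Mcm4, Pik3c2b, Ankdd1b and Tmem169. Cntnap4, a neurexin-family gene of interneurons, had 43.7 ± 4.85 in saline mutants and 58.3 ± 5.50 under UNC0642 (SD, n = 3 each), a log2 fold change of 0.41 (SE 0.11). Acan, the core protein of perineuronal nets, had 2.69 ± 0.823 and 1.16 ± 0.474 (SD, n = 3 each), a log2 fold change of -0.95 (SE 0.25). Adgrl4, an endothelial receptor, stood at -0.54 (SE 0.16) and the replication factor Mcm4 at -0.49 (SE 0.15). Dynlt1b belongs to a family of near-identical copies, and its value is uncertain. In limma, 0 genes were called in either direction, with 278 at an unadjusted p under 0.05, and limma-voom on the recovered reads also called 0. The 278 are a smaller share of the 14444 genes than the 0.05 that no change would give. Simulated changes were tested for saline mutant against wild type only. The power of this comparison, and of treated mutant against wild type, was therefore not measured. Within the 5 mutant libraries on 1 side of the division (3 saline, 2 UNC0642), limma-voom again called 0, with 864 at an unadjusted p under 0.05.

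Treated mutants were compared with wild type to ask what distance from wild type remained. In the deposited values, a mutant change of 1 that UNC0642 reverses in full shows here as -0.25 in place of 0. The values below therefore do not give that distance directly. Meningeal fibroblast markers were higher (18 of 19 positive, median 0.44, camera adjusted p = 3.8e-05, and adjusted p = 0.65 with an estimated correlation), Dcn by 0.67 (SE 0.20), Slc13a4 by 0.75 (SE 0.26) and Aldh1a2, a retinoic acid synthase, by 0.61 (SE 0.21). Heat shock and unfolded protein response genes were lower (22 of 24 negative, median -0.23, adjusted p = 1.3e-06), Sdf2l1 by a log2 fold change of -0.69 (SE 0.17), Hspa5 by -0.40 (SE 0.13) and Xbp1, the transcription factor of that response, by -0.29 (SE 0.09). This list and the next 3 had adjusted p = 0.65 with an estimated correlation. Ribosomal protein genes (64 of 66 positive, median 0.09), oxidative phosphorylation genes (53 of 56 positive, median 0.11) and sterol synthesis genes (22 of 23 positive, median 0.11) were higher, at adjusted p of 1.3e-06, 2.3e-05 and 0.00014, with Rpl14 at 0.40 (SE 0.15), Ndufa7 at 0.23 (SE 0.11) and Fdft1 at 0.27 (SE 0.09).

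Channel genes were lower in treated mutants than in wild type (32 of 39 negative, median -0.12, adjusted p = 6.2e-05), with Kcna1 at -0.31 (SE 0.10). The list had adjusted p = 0.65 with an estimated correlation. Other histone lysine methylases (23 of 29 negative, median -0.17), autism risk genes (39 of 50 negative, median -0.10), nuclear-retained long RNAs (10 of 10 negative, median -0.20), germline genes (7 of 7 negative, median -0.25) and astrocyte markers (18 of 23 negative, median -0.10) were lower, at adjusted p of 0.00094, 0.0018, 0.016, 0.025 and 0.046, against adjusted p = 0.65 with an estimated correlation (0.79 for astrocyte markers). Kmt2a stood at -0.39 (SE 0.14), Arid1b at -0.23 (SE 0.08), Mirg at -0.46 (SE 0.19), Brdt at -0.25 (SE 0.12) and S100b at -0.26 (SE 0.08). Clustered protocadherins were higher (38 of 53 positive, median 0.11, adjusted p = 0.042), Pcdhb20 by 0.36 (SE 0.13), and had adjusted p = 0.65 with an estimated correlation. With an estimated correlation 0 lists were called, and fry called 0. Without UNC0642 replicate 2 the number called was 5 in place of 13. With the division as a term, where this comparison is UNC0642 replicate 3 against wild type, meningeal markers stood at 0.96 and astrocyte markers turned to 0.12 (adjusted p = 0.0069). These had adjusted p = 0.33 and 0.89 with an estimated correlation. The calls ended for oxidative phosphorylation (-0.01, adjusted p = 0.8), germline genes (-0.30, 0.4), autism risk genes (0.02, 0.83), protocadherins (0.03, 0.68) and other methylases (-0.06, 0.19). The number called there was 12, with small RNAs (0.44), thalamic (0.23), hippocampal (0.28), microglia (0.09) and oligodendrocyte markers (-0.19) gained. These had adjusted p = 0.33, 0.33, 0.34, 0.89 and 0.89 with an estimated correlation.

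Among the 10 genes of smallest p between treated mutant and wild type, none called, were Inf2, Gabra2, Col4a2, Adgrl4, Mdga1, Tmem181b-ps, A730017C20Rik, Lypd1 and Nov. Inf2 had 130.3 ± 12.6 in wild type and 88.5 ± 15.6 in treated mutants, and Gabra2 had 64.55 ± 4.67 and 39.8 ± 11.05 (SD, n = 3 each), log2 fold changes of -0.56 (SE 0.11) and -0.72 (SE 0.14). Col4a2, a basement membrane collagen, stood at -0.49 (SE 0.10), the adhesion gene Mdga1 at -0.60 (SE 0.13) and Lypd1 at 0.50 (SE 0.12). In limma, 0 genes were called, with a smallest adjusted p of 0.59 and 1204 genes at an unadjusted p under 0.05, and limma-voom on the recovered reads called 14. Without UNC0642 replicate 1, 4 were called, Mgp higher by 1.07 and Gabra2, Inf2 and Tmem181b-ps lower by log2 fold changes of -0.93, -0.70 and -0.98, and the adjusted set as a term gave these 4 genes as well. On the wild-type side of the division there is a single treated library, UNC0642 replicate 3, so a comparison there takes its spread from wild type alone and tests no group difference.

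Whether UNC0642 moved genes against the genotype was asked of each gene in both comparisons. Because 0 genes were called in either, 0 were called in opposite directions and 0 in the same direction. Across the 14444 genes, which are not independent replicates, the fold changes of genotype and treatment correlated at 0.17 with a covariance of 0.0029. Both comparisons contain the saline mutant libraries, which alone gave a correlation of -0.50 and a covariance of -0.0135 in 100 simulations with no effect, and -0.10 and -0.00134 once the set adjustment was applied. These simulations, like the other no-change values below, held no division of the libraries. In the deposited values UNC0642 replicate 2 was adjusted apart from its side of the division. What remains of the division moves both comparisons the same way, so -0.10 is no reference for 0.17. With the saline mutant libraries divided so that none was shared, the 6 assignments gave correlations of 0.40 to 0.57. The set adjustment alone gives 0.40 to 0.46 for libraries with no change. Leaving out UNC0642 replicate 2 turned the correlation to -0.30 (-0.27 with no change). Leaving out saline mutant replicate 1, 2 or 3 turned it to -0.11, -0.12 and -0.21 (-0.41 with no change). A correlation of 0.61 was reached without UNC0642 replicate 1 (0.40 with no change). For recovered reads with the division as a term it was -0.70, against -0.62 with no change.

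Markers of cell types and neighbouring tissue were scored per library as the mean log2 difference from wild type. Meningeal fibroblast markers scored 0.50, 0.47 and 0.30 in the saline mutants and -0.16, 0.45 and 0.92 under UNC0642, against -0.09, -0.25 and 0.34 in wild type. Astrocyte markers ran from -0.21 to 0.29 within the wild-type libraries, and oligodendrocyte markers from -0.59 to 0.35 within the saline mutants. Deep-layer markers scored 0.18, 0.18 and -0.09 under UNC0642 and -0.19, 0.07 and 0.00 in the saline mutants. In exact two-sided permutation tests, whose smallest possible p is 0.1, 0 of the 51 differences passed 0.05, and the smallest Benjamini-Hochberg adjusted p was 0.94. In the recovered reads, where the division counts as genotype, the largest saline mutant score difference from wild type was -1.17 in small structural and ribosomal RNAs, a list with 2 measured members (-0.19 deposited). The median of this list, a sign of RNA depletion or quality, turned to 0.74 with the division as a term. Oligodendrocyte, oligodendrocyte precursor and nuclear-retained long RNA scores differed by -0.70, -0.29 and -0.55 (-0.01, -0.02 and -0.15 deposited), at p of 0.2, 0.2 and 0.1. Small RNA, red blood cell (0.21) and sex-linked (-0.20) scores also had p of 0.1, and the smallest adjusted p was 0.82.

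**Figure D4:**
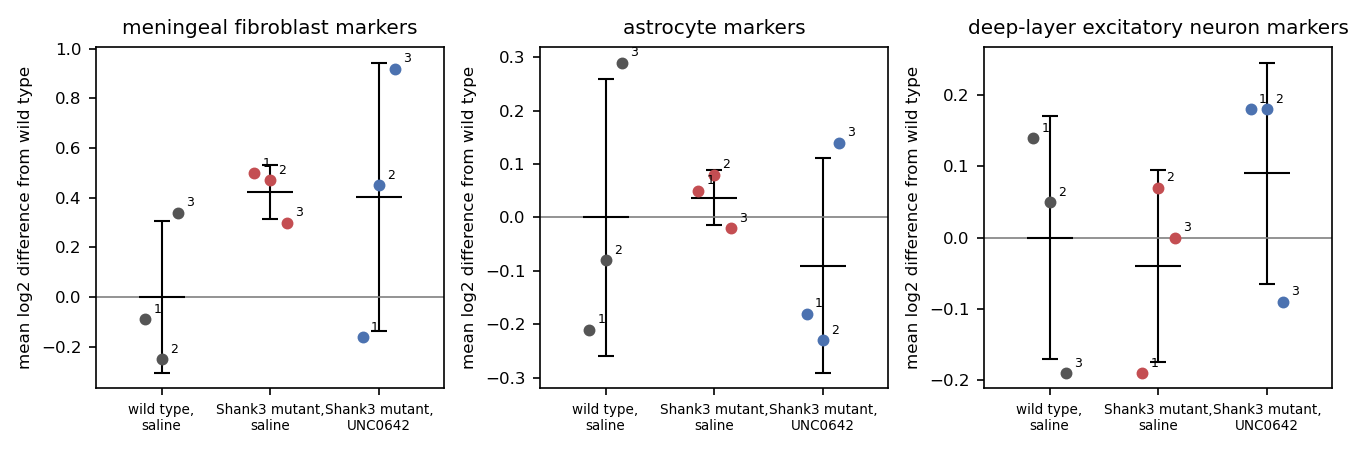
Mean log2 difference from the wild-type mean (vertical axes, not starting at the same value) of 3 marker lists in each library, with points numbered by replicate, and the mean (bar) and SD (whiskers) of each group of 3. Meningeal markers range from -0.16 to 0.92 among the 3 UNC0642 libraries and from 0.30 to 0.50 among the saline mutants.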

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

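The alternatives that use the adjusted set, the recovered reads with or without their division, other pseudocounts or a renewed adjustment were chosen after the results were seen. In every alternative run, 0 genes were called between UNC0642 and saline mutants. A gene counted as changed in opposite directions needs a call in both comparisons. That count was therefore 0 by definition in each alternative and says nothing about a reversal. Between saline mutant and wild type, 0 genes became 5 with only the 2 groups compared, 1758 in limma-voom on the recovered reads and 1987 in limma-trend on them, and stayed 0 without any 1 library. Between treated mutant and wild type, 0 became 14 in both of these fits on recovered reads, 4 with the adjusted set as a term, 4 with the division as a term (UNC0642 replicate 3 against wild type), 2 on 1 side of the division (a single treated library, so no group test), and 0 to 4 without 1 library. The correlation of fold changes, 0.17, was -0.71 in limma-voom and -0.69 in limma-trend on the recovered reads (-0.50 with no change for both). It was -0.69 with the adjusted set as a term (-0.78 with no change), -0.70 with the division as a term (-0.62) and -0.54 after the renewed adjustment (-0.50). With no shared library it was 0.49 on average (0.40 to 0.46), and without 1 library -0.30 to 0.61 (-0.41 to 0.40). All no-change values are for libraries without a division. In the fits on recovered reads without that term, the division by itself moves the 2 comparisons in opposite directions, as UNC0642 replicate 3 lies with wild type. The -0.50 therefore cannot tell such a division from a reversal. The cause was not tested for these changes, except that the set adjustment by its construction shrinks differences between its sets.

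Gene lists called without 1 library numbered 5 to 16 (10 with all libraries) for saline mutant against wild type, 3 to 20 (15) for UNC0642 against saline and 5 to 17 (13) for treated mutant against wild type. With an estimated correlation, and with fry, they numbered 0 in each comparison. For UNC0642 against saline they numbered 8 with the adjusted set as a term, 8 in limma-trend on the recovered reads and 9 after the renewed adjustment, which gave 5 for treated mutant against wild type.

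Some called lists turned in direction. In saline mutant against wild type, immediate early genes stood at 0.04 in both fits on recovered reads and 0.01 with the division as a term (-0.13 to -0.03 without 1 library), and autism risk genes at 0.02 with the division as a term and 0.00 after the renewed adjustment. For UNC0642 against saline, limma-voom and limma-trend on the recovered reads both gave other histone methylases 0.06, autism risk genes 0.05, oxidative phosphorylation -0.11, ribosomal proteins -0.10, oligodendrocyte precursors 0.12 and endothelial markers 0.02. Ribosomal proteins stood at -0.03 with the adjusted set, -0.07 with the division and -0.04 after the renewed adjustment, and oxidative phosphorylation at -0.01 in the latter 2. Without 1 library, other histone methylases ranged from -0.13 to 0.01, autism risk genes from -0.09 to 0.01 and oxidative phosphorylation from -0.01 to 0.11, each turning without UNC0642 replicate 2. In treated mutant against wild type, oxidative phosphorylation stood at -0.01 with the division and -0.00 after the renewed adjustment, and astrocyte markers at 0.12 with the division and -0.20 to 0.03 without 1 library, turning without wild-type replicate 3. The cause was not tested. Over all 111 list results and their alternatives (2442 comparisons), 1934 kept their direction and stayed either called or uncalled. Of the rest, 218 lost the call, 82 gained it, 179 uncalled ones turned and 29 called ones turned. No named gene was called in the main fit, so none had a call to keep. Of 3906 comparisons for 186 named-gene results, 3741 kept direction and stayed uncalled, 97 gained a call and 68 turned in sign.

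With the replicate block, 0 genes were called in each of the 3 comparisons (22, 262 and 1121 at an unadjusted p under 0.05) and the lists called numbered 9, 14 and 13. Libraries with a number in common were not paired: 2 of 9 pairs correlated over 0.1 (range -0.19 to 0.31) and, by deviations from group means, 3 of 9 libraries lay closest to their own number among the libraries of other groups. The DESeq2 Wald test was not run, and the fit without a filter is the one reported. Depth was 12035098 to 16165483 reads, so genes of few reads carry the prior more than their own counts.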

Other observations

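All tests in this part were chosen after the results they bear on were seen. In the recovered reads with the division as a term, limma-voom called 4 genes between treated mutant and wild type. With that term the comparison is UNC0642 replicate 3 alone against wild type, with the spread taken from the other libraries, so the level of that library chose these genes, and the other 5 mutant libraries lie on the other side of the division. Gabra2, a GABA-A receptor subunit, had 73.3 to 84.1 CPM of recovered reads in wild type and 37.3 to 45.5 in the mutant libraries. Inf2, a formin, had 140 to 170 against 86.1 to 99.0, and Robo3, an axon guidance receptor, 24.8 to 33.0 against 8.56 to 16.0. Mgp, a calcification inhibitor of vessels, had 7.44 to 9.0 against 11.4 to 20.9; its highest value is in UNC0642 replicate 3, which also has the highest meningeal score (0.92), so Mgp was not told apart from the meningeal markers (median 0.96 in this fit). Their log2 fold changes were -0.81, -0.77, -1.75 and 1.37 (limma adjusted p of 0.021, 0.021, 0.025 and 0.021), while UNC0642 and saline mutants differed by 0.02, 0.07, 0.23 and -0.02 (adjusted p of 0.999 each). The genes lie on chromosomes 5, 12, 9 and 6, and Shank3 on 15. Gabra2 is known to differ in expression between inbred mouse strains, and the labels give no strain for either genotype.

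Cell type lists between UNC0642 and saline mutants were also read with the division as a term. With that term the comparison rests on 2 UNC0642 libraries (replicates 1 and 2) and the 3 saline mutant libraries, without UNC0642 replicate 3. Deep-layer markers had a median log2 fold change of 0.24 and upper-layer markers of -0.17 (camera adjusted p of 5.85e-08 and 8.25e-08), and oligodendrocyte markers had 0.43 (adjusted p = 1.57e-05). Astrocyte markers stood at -0.17 and sterol synthesis genes at 0.10 (adjusted p of 6.14e-07 and 1.98e-05), glutamate receptor and scaffold genes at -0.08 (adjusted p = 7.88e-05). Small structural and ribosomal RNAs, a sign of RNA depletion or quality, moved in the same fit, at -0.30 (adjusted p = 0.00682), as did olfactory or immature neuron markers at -0.17 (0.00569), circadian genes at -0.09 (0.00682) and microglia markers at -0.09 (0.045), among 14 lists called. These p-values use the preset correlation; estimated, it left 0 of the 37 lists called, at a smallest adjusted p = 0.16 with an estimated correlation. Between saline mutant and wild type these lists ran the other way, deep and upper layers at -0.36 and 0.15, oligodendrocyte markers at -0.61 and astrocyte markers at 0.33 (adjusted p of 2.23e-05 and 3.59e-07 for the latter 2), as shared saline mutant libraries give by chance. The latter 2 had adjusted p = 0.66 and 0.6 with an estimated correlation, and the layer lists 0.53 (deep) and 0.3 (upper). Heat shock and unfolded protein response genes, called in both comparisons with the preset correlation, ran the same way. Their medians were -0.12 for UNC0642 against saline and -0.16 for saline mutant against wild type. These had camera adjusted p = 0.56 and 0.62 with an estimated correlation.

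UNC0642 replicate 2 lay far from the other libraries in the deposited values, with an SD over genes of 0.35 for its log2 deviations against 0.19 to 0.26. When the adjustment was made again with this library in the set of the saline mutants, its SD was 0.18, within the 0.18 to 0.22 of the others. Before the adjustment its correlation with its closest library was 0.42, where the others had 0.25 to 0.53. Libraries on 1 side of the division correlate through the division itself, so this value cannot exclude biology of that sample alone. By the fall of its SD, the spread of the UNC0642 group may come from the adjustment, and why the library was placed in that set stays open.

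For 19 genes the recovered reads lay at least 8-fold apart between wild type and saline mutants. Of the 11 lower in wild type 9 are pseudogenes (81.8%, against 0.562% of other genes, Fisher's exact test p = 5.29e-19). Reads moved between genes and their pseudogenes could give this. Of the 7 annotated genes lower in saline mutants 0% are pseudogenes and 3 are long noncoding RNAs. Gene type alone does not exclude moved reads there, as Dynlt1a, among them, is of the same family of near-identical copies as Dynlt1b. A segment of another strain around Shank3, with these gaps in its own genes, is argued against, as 0% of 18 genes lie on chromosome 15 (3.93% of other genes do). The genes were chosen for 8-fold gaps, so they do not show whether such a segment is present. Genotype with every label right is argued against too, since UNC0642 replicate 3 lies with wild type for 19 of 19 genes. A batch of libraries or of processing, and a wrong label of that library, stay open.

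Meningeal fibroblast markers were higher in the deposited values of most mutant libraries. Their members moved together within groups, with a mean correlation of 0.75 against 0.01 on average and 0.26 at most for 10000 random lists. Of the 19, 0 are in another list and 18 exceed a value of 1 in every library. Markers of cortical cell types moved together as well, with estimated correlations of 0.79 for oligodendrocyte and 0.69 for astrocyte markers. Random lists are therefore a weak comparison, and the correlation cannot tell meninges left on some samples from another cause. The most abundant, Ptgds, had 255.5 to 471 in wild type, 431 to 545 in saline mutants and 254.5 to 700.3 under UNC0642, and Igf2 43.4 to 76.1, 62.1 to 82.1 and 48.0 to 115. A genotype effect and meninges left on some samples cannot be told apart. The deposited difference between saline mutant and wild type is fixed by the UNC0642 libraries. Besides, 1 mutant library lies at -0.16, below the wild-type mean, and that single value decides nothing.

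The 10 splits of each pair of groups are too few for a share under 0.05. For genes the real count was 0 in each comparison, which 10 of 10 splits reach by definition, so these splits say nothing; the highest other count was 0 for saline mutant against wild type and 1 for each of the others. For lists the real values were 10, 15 and 13, and the highest of the other splits 13, 12 and 15, with 4, 1 and 5 splits reaching the real value. The set adjustment shrinks differences between its sets, and the real split of saline mutant and wild type follows these sets. Other splits mix the sets, so the list counts are not like for like and decide nothing about chance.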
